A study of Mus musculus with 12 samples.

How the data were processed

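RNA of 12 libraries of mouse V6.5 embryonic stem cells was sequenced with paired ends, per the labels, from cells on gelatin in serum medium with LIF, CHIR99021 and PD0325901. The labels place 3 libraries (A, B and C) in each of 4 groups: Tet1KO, DKO (numbered 41) and N1300T (numbered 49 and 81), and what the numbers stand for is not given in the sources used here. The values are counts of reads per gene, as deposited by the authors in 1 table of 35976 gene symbols, not normalized. Per the submitters' processing notes the genome build was mm10 and DESeq2 was used. The aligner, the counter, the annotation and whether counting used strand are not given in the sources used here. In the deposited counts, even values outnumbered odd ones at the low end (5990 values of 1, 20282 of 2, 3467 of 3 and 9469 of 4), as would arise if most fragments added a count for each mate. Counting error from such counts is then understated, and a fit with all counts halved was added after this was seen.

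Total counts per library were 32951414, 42200418 and 41942466 for Tet1KO A, B and C and 57054862, 40675081 and 55660919 for DKO. They were 50100842, 37405732 and 31515011 for N1300T 49 and 50798498, 53408950 and 45291457 for N1300T 81. Genes encoded by the mitochondrion took 1.74% to 2.64% of the counts. The groups, comparisons, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added later. Every library of a group was used. The chi-square of counts between replicates was 2.03 to 2.92 per degree of freedom for genes of 20 to 50 counts, near the 2 that sampling alone would give if both mates were counted, and for genes of over 1000 counts 6.24 to 10.7 in Tet1KO, N1300T 49 and N1300T 81 and 2.88 to 5.67 in DKO. These exceed what sampling alone would give in repeated sequencing of 1 library, but do not tell separate cultures from separate libraries of 1 culture.

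All comparisons came from 1 fit of the 12 libraries with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, using TMM factors (0.979 to 1.02), filterByExpr by group, a quasi-likelihood fit with 8 residual and 9.11 prior degrees of freedom and 2-sided tests. The filter left 16014 genes that held 99.97% of the counts, and the biological coefficient of variation was 0.0859. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. N1300T stands for the mean of both preparations, each weighted equally, so its tests take their error from libraries and not from the 2 preparations. Principal components used log2 CPM with a prior count of 2, and the exact permutation test of the pseudo-F enumerated 84 splits. The 31 gene lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry, which tests whether members move on balance one way without comparing them with other genes. Members called were counted over all genes tested and adjusted over the list alone. Of the members, 9 had no match in the table. None of the 39 list results called by camera changed the sign of its median or of its majority of calls with RLE factors or library size alone.

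The lists were TET enzymes and base excision repair of oxidised pyrimidines, DNA methylation machinery, naive pluripotency, formative and primed pluripotency, two-cell-like state, germline genes under promoter methylation, imprinted genes, mesendoderm, primitive endoderm, trophoblast, neuroectoderm, fibroblasts (feeder cells), blood specification, p53 targets, homologous recombination and Fanconi repair, interferon response, Hox genes, ERK pathway, Wnt targets, LIF and STAT3 targets, S phase, G2 and mitosis, glycolysis and hypoxia, integrated stress response, heat shock, cholesterol synthesis, mitochondrially encoded, Y-linked, Rhox cluster, clustered protocadherins, and Polycomb and histone H3K27 enzymes. They share members, such as Lef1 in the formative and Wnt lists and Peg10 in the imprinted and trophoblast lists.

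Named genes were the 8 with the largest rise and the 8 with the largest fall per comparison (5 and 5 between 49 and 81). They had to be called, with at least 1 CPM in the higher group, no overlap between the libraries compared and no predicted or clone name. To these were added up to 3 called members of each list by adjusted p, the 8 highest and 8 lowest of the genes apart in both N1300T preparations, and Tet1, Tet2, Tet3 and Tdg. Outside that rule, Cdkn1a, Mdm2, Wnt8a and Sox3 in DKO against Tet1KO, Igf2 and Mdm2 in N1300T against DKO and Meg3 in N1300T against Tet1KO were chosen after their values were seen. Some genes that the rule takes are not reported here. Positions were looked up by symbol in RefSeq's table of GRCm38.p6, the assembly named mm10, which gave a chromosome for 97.4% of the tested genes. Where genes overlap or have near-identical copies the split of reads is uncertain, which concerns the clustered protocadherins (shared exons), Hspa1a and Hspa1b, Nlrp4a, Oas1a, Rbm12b1, Peg13 within Trappc9, H13 and Mcts2, Hydin with Gm21283 inside it, and Y-linked genes with X-linked paralogs.

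In simulated counts with the means and depths of these libraries, 50 genes at each fold were changed. These had a mean of at least 1 CPM, so recovery of genes below that was not measured. For N1300T against Tet1KO the test recovered 50%, 80%, 100% and 100% at folds of 1.25, 1.5, 2 and 4. It called 8 unchanged genes among 15764 tested genes, the changed ones included. For DKO against Tet1KO it recovered 28%, 68%, 100% and 100% (11 among 15740), for N1300T against DKO 46%, 84%, 98% and 100% (6 among 15756), and for 49 against 81 36%, 78%, 92% and 100% (13 among 15751). Alternatives fixed in advance were DESeq2 1.42.0, RLE factors, library size alone, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate letter as a block, limma-voom, a minimum fold of 1.5, leaving out each library, only the groups compared, and other groupings of the N1300T libraries. Chosen after seeing the data were halved counts, leaving out chromosomes 6, 8 and 11 (also together with Tet1KO A), the chromosome medians without single libraries or with other scaling, list calls and genes apart in Tet1KO without single libraries, the neighbours of imprinted genes with none left out, and the overlap of all lists with the genes apart.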

Results

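Mouse V6.5 embryonic stem cells, a male line, were kept on gelatin with LIF and inhibitors of MEK and GSK3 and profiled by paired-end sequencing of total RNA. TET enzymes oxidise 5-methylcytosine, and the study asked what expression of TET2 carrying a leukaemia-derived change, N1300T, does to the transcriptome. All 12 libraries lacked Tet1 by their genotype labels. They formed 4 groups of 3, with replicates lettered A, B and C. By the labels Tet2 was also knocked out in DKO (numbered 41), and N1300T libraries were numbered 49 or 81 under 1 genotype label. What the numbers stand for is not given, and each numbered set of 3 is called a preparation here. Total counts ran from 31515011 (N1300T 49 C) to 57054862 (DKO A), and 16014 genes were tested. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples. Tet1KO and DKO have 1 set of 3 libraries each, so an effect of genotype cannot be separated from other properties of those cells. Levels are in CPM ± SD with n = 3 (n = 6 for both N1300T preparations together), log2 fold changes are ± SE, and positions are on mm10.

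The 2 genes named by the genotypes were examined first. Tet2 (chromosome 3, 133463677 to 133545136) stood at 160.4 ± 19.3 CPM in Tet1KO, 94.5 ± 3.05 CPM in DKO, 135 ± 11.2 CPM in N1300T 49 and 142 ± 13.04 CPM in N1300T 81. It fell in DKO by 0.76 on the log2 scale against Tet1KO (SE 0.09, adjusted p 1.43e-05), with a transcript still present in each of the 3 DKO libraries. N1300T lay 0.55 ± 0.08 above DKO (adjusted p 0.000472), and its difference from Tet1KO of -0.21 ± 0.07 missed the threshold (adjusted p 0.0591). Tet1 (chromosome 10, 62804570 to 62887469) was counted in every group, from 153 ± 21.2 CPM in Tet1KO to 174 ± 6.19 CPM in DKO, and no comparison between groups called it. Counts summed over a gene do not show a short deletion or a single changed codon, so these levels check the labels only for a loss of transcript. Tet3, the remaining TET gene, fell in N1300T (-0.56 ± 0.12, adjusted p 0.00385) and in DKO (-0.51 ± 0.14, adjusted p 0.0202), from 8.45 ± 1.06 CPM to 5.73 ± 0.718 and 5.91 ± 0.563 CPM. Tdg, the glycosylase that removes oxidised cytosines, was not called in any of these comparisons (0.06 ± 0.07 in N1300T, -0.12 ± 0.08 in DKO, both against Tet1KO).

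**Figure D1:**
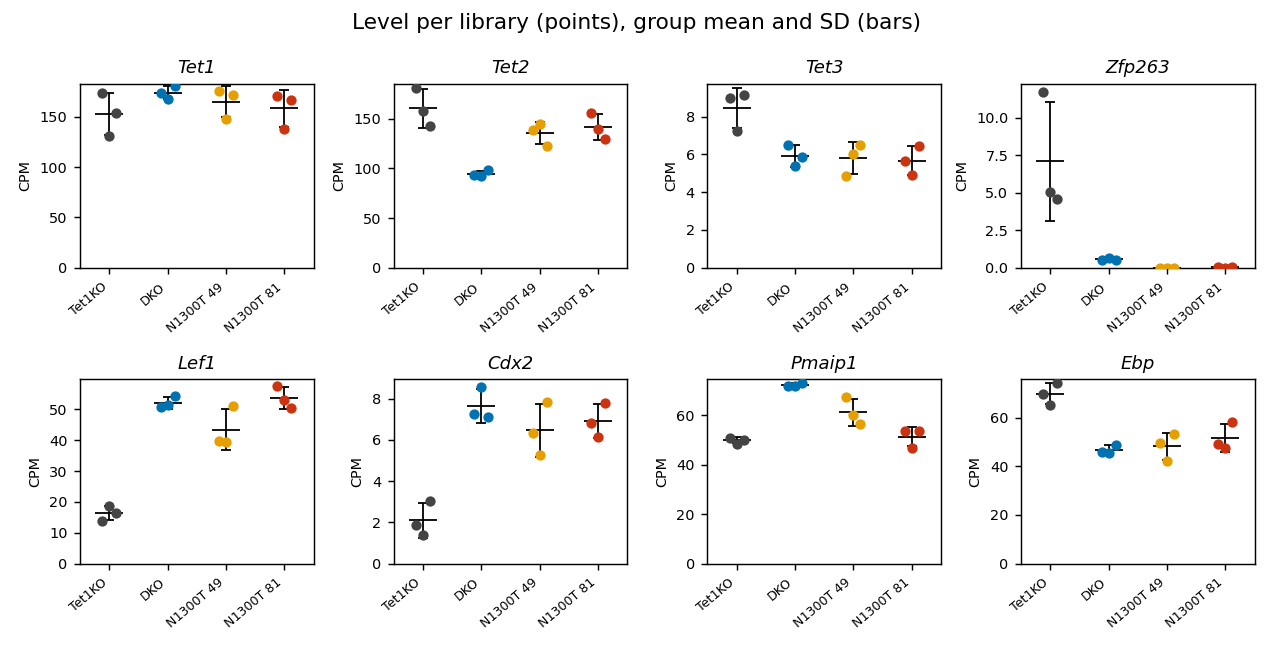
Expression in CPM (vertical axes, linear) of 8 named genes in each library of the 4 groups (points), with group mean and SD (bars). Tet2 is lowest in the 3 DKO libraries (94.5 CPM) and Tet1 is counted in all 12 libraries, while Zfp263, Lef1, Cdx2 and Ebp separate the 3 Tet1KO libraries from the rest.

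The series describes a separation of N1300T cells from both other genotypes in a principal component analysis. In the 500 most variable genes, the first component held 36.1% of the variance and set Tet1KO (mean score -23.9 ± 4.27) apart from DKO (5.22 ± 0.666), N1300T 49 (8.49 ± 1.499) and N1300T 81 (10.2 ± 1.59). The second, with 17.4%, ordered DKO (-13.005 ± 0.890), N1300T 49 (-0.121 ± 6.32) and N1300T 81 (11.9 ± 6.17), with Tet1KO at 1.24 ± 4.85. The third, with 9.99%, set N1300T 49 (11.5 ± 3.85) apart from N1300T 81 (-6.83 ± 1.82), DKO (-4.56 ± 0.336) and Tet1KO (-0.125 ± 3.07). It thus separated the 2 N1300T preparations from each other. In an exact permutation test of the distances between libraries over all tested genes, N1300T differed from Tet1KO (pseudo-F 3.52, exact p 0.0119, the smallest of 84 splits of 6 against 3) and from DKO (pseudo-F 2.02, exact p 0.0238), where 1 other split gave a larger pseudo-F of 2.14. Mean distances between libraries were 57.6 for N1300T 49 to DKO, 57.8 for 49 to N1300T 81 and 58.6 for 81 to DKO. They include the spread within groups (mean distance 43.0 in DKO, 56.3 in 49 and 53.1 in 81), so they do not rank the groups by nearness. Gene by gene, 58 genes were called between 49 and 81, beside 366 between 49 and DKO and 379 between 81 and DKO. The 2 tests treat the 6 N1300T libraries as independent, although they come from 2 preparations.

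**Figure D2:**
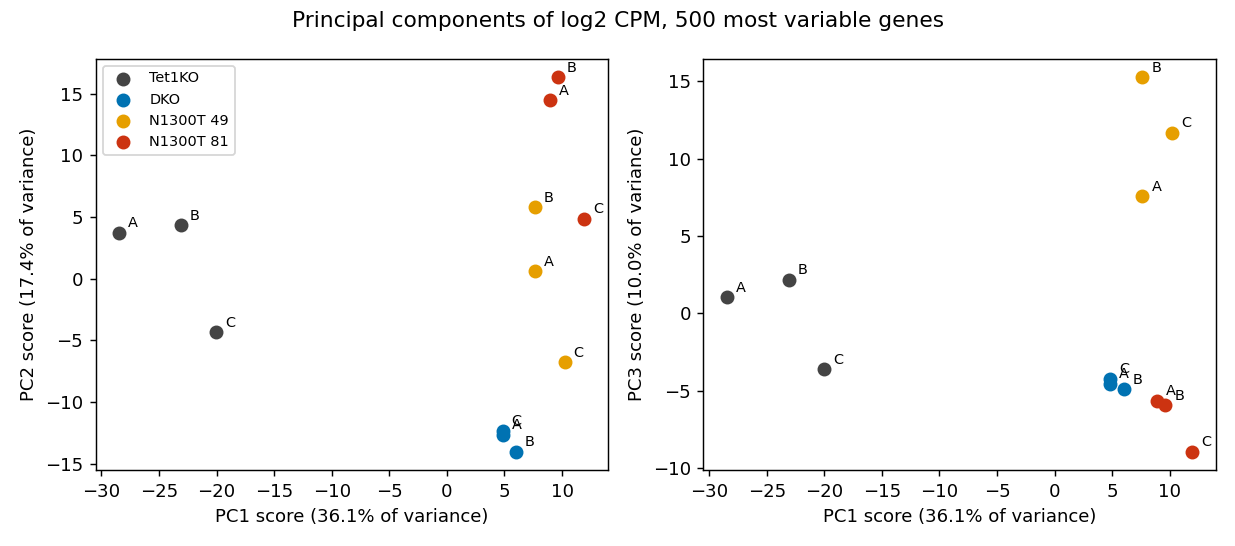
Scores of the 12 libraries (points, coloured by group and marked with the replicate letter) on the first 3 principal components of log2 CPM of the 500 most variable genes, with the share of variance on each axis. Tet1KO libraries have the lowest scores on the first component (group mean -23.9).

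N1300T against Tet1KO compares the mutant genotype with 1 whose label names no change in Tet2. Tbx15, a T-box factor, rose by 4.25 ± 0.25 (adjusted p 6.79e-09) from 0.178 ± 0.0769 to 3.35 ± 0.406 CPM. Hand1 rose by 2.18 ± 0.25 and Wt1 by 2.13 ± 0.22. Lef1, a nuclear effector of Wnt signalling, rose by 1.56 ± 0.10 (adjusted p 1.35e-08) from 16.3 ± 2.37 to 48.6 ± 7.39 CPM, and Cdx2, a caudal-type homeobox factor, by 1.67 ± 0.20. Enpp2, which encodes autotaxin, and Pde4b, a cAMP phosphodiesterase, rose by 2.93 ± 0.30 and 2.90 ± 0.32, and Comp and Dpysl4 by 2.23 ± 0.24 and 2.03 ± 0.19. Among the genes that fell were As3mt, the arsenite methyltransferase (-3.21 ± 0.18), Hnf4a, a nuclear receptor (-3.15 ± 0.41), Slc38a5, an amino acid transporter (-3.30 ± 0.38), Serpina3m (-2.99 ± 0.39), Ufsp2 (-3.12 ± 0.31) and Zfp560 (-3.55 ± 0.48). Zfp263, a zinc-finger gene (chromosome 16, 3744099 to 3750790), had 781 counts in the 3 Tet1KO libraries, 88 in the 3 DKO libraries and 4 in the 6 N1300T libraries, with Tet1KO levels of 7.11 ± 3.98 CPM. Dnmt3a, a de novo DNA methyltransferase, fell by 0.63 (SE 0.07, adjusted p 5.54e-06) from 68.1 ± 5.98 to 44.2 ± 4.13 CPM.

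In all, 2520 genes were called by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 1232 higher and 1288 lower in N1300T. Of these, 223 were over 2-fold higher and 235 over 2-fold lower. N1300T 49 and N1300T 81 taken singly gave 1739 and 1951 calls against Tet1KO, with 1193 shared in the same direction and 3 in opposite directions. Without Tet1KO A the count fell to 1388, and 234 genes exceeded a fold of 1.5 by more than their error.

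Among the gene lists in N1300T against Tet1KO, p53 targets rose, with 12 of 29 members called higher (17 higher and 2 lower when adjusted over the list alone), including Ak1 (0.37 ± 0.05), Ei24 (0.30 ± 0.05) and Bbc3, a pro-apoptotic BH3-only gene (0.49 ± 0.08). The set test gave an adjusted p of 7.70e-05, and 0.295 with an estimated correlation, and the other 4 rising lists named here also lost their call with it (adjusted p 0.276 to 0.371). The p53 count was 4 without Tet1KO A, 6 higher and 1 lower without Tet1KO B, and 10 higher and 1 lower without N1300T 49 C or 81 C. Formative and primed pluripotency genes had 7 higher and 1 lower of 20 (8 and 3 adjusted over the list alone, adjusted p 0.00389), with Lef1, Sall2 (0.82 ± 0.07) and Cldn6 (0.81 ± 0.08) among the risers, while Dnmt3a was the member that fell (4 fell without N1300T 81 C). Wnt targets had 6 higher and 2 lower of 19 (8 and 2 adjusted over the list alone, adjusted p 0.0169), led by Notum, a secreted Wnt inhibitor (1.01 ± 0.10), and Tnfrsf19 (0.87 ± 0.08). The Wnt count was 3 higher and 2 lower of 12 off chromosomes 6, 8 and 11. Mesendoderm genes had 5 higher and 2 lower of 17 (6 and 2 adjusted over the list alone, adjusted p 0.0299), with Evx1 up (1.32 ± 0.26) and Lefty2, an inhibitor of Nodal signalling, down (-0.56 ± 0.10). Mesendoderm had 1 lower without Tet1KO A, Tet1KO B, N1300T 49 A or N1300T 49 C. Hox genes had 4 higher of 9 (5 adjusted over the list alone, adjusted p 0.00257), including Hoxd4, whose 69 counts against 2 give a ratio of 15.0 with a 95% counting interval of 4.01 to 127. That interval takes counts as independent and is too narrow if both mates were counted. Both Tet1KO counts came from Tet1KO A. The Hox count was 2 without Tet1KO A, and 1 of 5 off chromosomes 6, 8 and 11.

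Lists that fell in N1300T against Tet1KO included S phase genes, with 13 lower of 30 (16 adjusted over the list alone, adjusted p 2.37e-05), such as Ccne1 (-0.40 ± 0.06), Mcm4 (-0.31 ± 0.05) and Pcna (-0.28 ± 0.05), which act in replication entry and at the fork. With an estimated correlation this call and those of the 3 lists that follow were lost (adjusted p 0.291 to 0.295). Cholesterol synthesis had 7 lower of 24 (8 adjusted over the list alone, adjusted p 0.000433), including the sterol enzymes Ebp (-0.48 ± 0.08), Dhcr7 (-0.41 ± 0.07) and Sc5d (-0.38 ± 0.06). The integrated stress response had 8 lower and 1 higher of 29 (10 and 1 adjusted over the list alone, adjusted p 0.00320), with Mthfd2 (-0.56 ± 0.07), Phgdh, the first enzyme of serine synthesis (-0.43 ± 0.06), and Slc7a5 (-0.42 ± 0.07). LIF and STAT3 targets had 7 lower and 1 higher of 18 (8 and 1 adjusted over the list alone, adjusted p 0.0241), with Bcl3 (-0.36 ± 0.07) down and Il6st, the shared signalling receptor of LIF, up (0.28 ± 0.06). The Y-linked list kept its call with an estimated correlation (adjusted p 0.0295). Without Tet1KO A, whose medians stood apart on chromosomes 6, 8 and 11 (0.18, 0.13 and -0.12), calls fell to 6 for S phase, 4 lower and 1 higher for LIF and STAT3 targets and 3 for the integrated stress response. LIF and STAT3 targets had 4 lower and 2 higher without Tet1KO C and 6 lower and 2 higher without N1300T 81 B. The integrated stress response had 5 lower and 1 higher without Tet1KO B, and its higher member lost its call without Tet1KO A or C, DKO A, B or C, or N1300T 49 B or C.

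**Figure D3:**
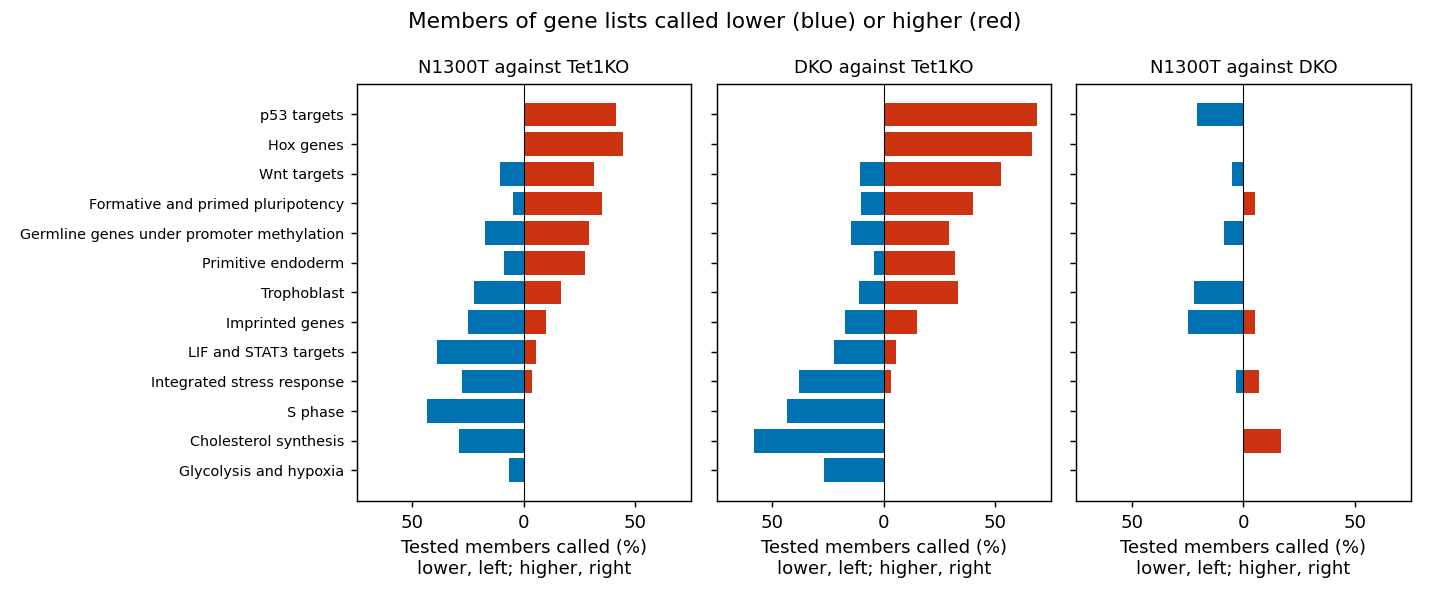
Percent of the tested members of 13 gene lists called lower (blue, to the left) or higher (red, to the right) in each of 3 comparisons. Cholesterol synthesis has 14 of 24 members lower in DKO against Tet1KO and 4 higher in N1300T against DKO.

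Comparing DKO with Tet1KO addresses the Tet2 knockout label in cells that share the Tet1 knockout label. Tbx15 rose by 3.95 ± 0.27 (adjusted p 1.56e-07) to 2.700 ± 0.141 CPM, Enpp2 by 3.65 ± 0.31, Pde4b by 3.26 ± 0.33, and Pou4f3, a POU-domain factor, by 3.04 ± 0.43, with Hand1 (2.48 ± 0.27), Comp (2.47 ± 0.25) and Sp8 (2.30 ± 0.37) also among the largest rises. Genes that fell included Slc38a5, with 6 counts in the DKO libraries and 182 in Tet1KO, Zfp263 (-3.63 ± 0.36), Serpina3m (-3.43 ± 0.49), Ufsp2 (-2.71 ± 0.37), Khdc3 (-2.62 ± 0.24, from 25.7 ± 6.39 to 4.199 ± 0.748 CPM), Nkx6-3 (-2.59 ± 0.38), Tgfbi (-2.49 ± 0.34) and Card6 (-2.48 ± 0.22). Dnmt3a fell by 0.79 (SE 0.08, adjusted p 4.69e-06) and Dnmt3b, the other de novo methyltransferase, rose by 0.48 ± 0.11. Pfkp, the platelet phosphofructokinase, fell from 165 ± 71.98 to 33.8 ± 0.592 CPM (-2.29 ± 0.38).

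The comparison called 2399 genes, 1259 higher and 1140 lower in DKO (edgeR, adjusted p under 0.05), of which 320 were over 2-fold higher and 230 over 2-fold lower. Scaling by library size alone moved the share of higher calls from 52.5% to 63.8%. The count fell to 1386 without Tet1KO A, to 1420 without DKO A and to 1402 without DKO C, and 238 genes exceeded a fold of 1.5 by more than their error.

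Cholesterol synthesis fell in DKO, with 14 of 24 members lower (16 adjusted over the list alone, adjusted p 7.33e-09), including Msmo1 (-0.63 ± 0.10) and Dhcr7 (-0.58 ± 0.08). With an estimated correlation the adjusted p was 0.164, and the other 6 lists named here also lost their call (adjusted p 0.164 to 0.181). For p53 targets 20 of 29 were higher (22 higher and 1 lower adjusted over the list alone, adjusted p 7.33e-09), among them Pmaip1 (0.54 ± 0.07), Trp53inp1 (0.60 ± 0.09), Cdkn1a, an inhibitor of cyclin-dependent kinases (0.43 ± 0.08), and Mdm2, the ubiquitin ligase of p53 (0.56 ± 0.12). Without Tet1KO B, 1 p53 target was also called lower. Wnt targets had 10 higher and 2 lower of 19 (11 and 2 adjusted over the list alone, adjusted p 0.000263), with Axin2 (0.65 ± 0.08), T, or Brachyury (1.36 ± 0.20), and Wnt8a (1.84 ± 0.33). They had 1 lower without any 1 of the 3 Tet1KO or 3 DKO libraries, and 6 higher and 2 lower of 12 off chromosomes 6, 8 and 11. Formative and primed genes had 8 higher and 2 lower of 20 (10 and 2 adjusted over the list alone, adjusted p 0.00127), with Sox3 (1.30 ± 0.16) and Lef1 (1.67 ± 0.11) higher. Germline genes under promoter methylation had 10 higher and 5 lower of 34 (11 and 5 adjusted over the list alone, adjusted p 0.0378), led by Meioc (1.43 ± 0.10), Tdrd1, a piRNA pathway gene (1.59 ± 0.21), and Tex15 (0.96 ± 0.12). Germline calls were 9 higher and 3 lower without Tet1KO A or DKO B, and 8 higher with 2 and 3 lower without DKO A and C. Mesendoderm had 5 higher and 2 lower of 17 (6 and 2 adjusted over the list alone, adjusted p 0.0312, and 2 and 2 of 14 off chromosomes 6, 8 and 11). Blood specification had 3 higher and 2 lower of 17 (4 and 2 adjusted over the list alone, adjusted p 0.0295), with Cebpa (1.52 ± 0.21) and Myb (0.69 ± 0.10) higher and Gata2 lower (-1.12 ± 0.16). Blood specification had 1 lower without Tet1KO B, DKO A, DKO B or DKO C.

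The other 8 lists called in DKO against Tet1KO lost their call with an estimated correlation (adjusted p 0.164 to 0.711). S phase had 13 lower of 30 (17 adjusted over the list alone, adjusted p 7.57e-07), with Mcm5 (-0.31 ± 0.05) and Mcm3 (-0.27 ± 0.06), and 8, 7 and 8 without Tet1KO A, DKO A and DKO C. The integrated stress response had 11 lower and 1 higher of 29 (13 and 2 adjusted over the list alone, adjusted p 0.00139), and 5, 5 and 4 lower without the same libraries and 7 without Tet1KO B. Its higher member lost its call without Tet1KO A or C, a DKO library or N1300T 81 A, and 2 were higher without N1300T 49 A, 49 C or 81 C. Hox genes had 6 higher of 9 (7 adjusted over the list alone, adjusted p 3.22e-05), with Hoxb13 (1.64 ± 0.35) and Hoxc13 (0.75 ± 0.17), and 3 without each of Tet1KO B, DKO B and DKO C. Off chromosomes 6, 8 and 11 the Hox count was 2 of 5. Glycolysis and hypoxia had 8 lower of 30 (9 lower and 1 higher adjusted over the list alone, adjusted p 0.0156), with Gapdh (-0.29 ± 0.07) and Hk2 (-0.33 ± 0.08), and 2, 2, 4 and 3 without Tet1KO A, Tet1KO B, DKO A and DKO C. The glycolysis count was 5 of 22 off chromosomes 6, 8 and 11. Primitive endoderm had 7 higher and 1 lower of 22 (9 and 1 adjusted over the list alone, adjusted p 0.00929), with Gata4 (1.47 ± 0.20), and 2, 4, 3, 3 and 5 higher without Tet1KO A, Tet1KO B, DKO A, DKO B and DKO C. The lower member lost its call without Tet1KO A or C or any 1 DKO library. Trophoblast genes had 6 higher and 2 lower of 18 (8 and 3 adjusted over the list alone, adjusted p 0.0427), with Cdx2 (1.86 ± 0.21), and 4 higher and 1 lower without Tet1KO A or DKO A and 5 and 1 without DKO C. Fibroblast markers had 4 higher of 18 (4 adjusted over the list alone, adjusted p 0.0156), with Fbln2 (0.88 ± 0.13) and Twist1 (0.90 ± 0.24) at 10.8 and 2.11 CPM in DKO, and 1 and 2 without Tet1KO A and DKO C (2 of 15 off chromosomes 6, 8 and 11). TET enzymes and base excision repair had 5 lower of 24 (7 lower and 1 higher adjusted over the list alone, adjusted p 0.0116), Tet2 itself included, and 3, 3, 2, 3 and 1 without Tet1KO A, Tet1KO B, DKO A, DKO B and DKO C.

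Changes against Tet1KO overlapped between N1300T and DKO. Lef1, Tbx15, Enpp2, Pde4b, Comp and Hand1 rose and Dnmt3a, Serpina3m, Slc38a5, Ufsp2 and Tet3 fell in both comparisons. The 2 comparisons shared 1412 genes called in the same direction, 737 higher and 675 lower, with 7 in opposite directions. Independent lists of these sizes would share 189 genes in the same direction, and 20 simulations of unchanged groups against the same controls shared 0.1 genes on average (at most 1). These simulations drew all libraries from 1 mean per gene and called 0.4 and 0.35 genes per comparison on average, so few could be shared. They cannot show the overlap that a Tet1KO set unlike the other cells would give. The fold changes correlated at 0.76 across genes, which are not independent replicates, beside 0.60 in the simulations, and their covariance was 0.173 beside 0.032, a difference of 0.141. The 3 Tet1KO libraries cannot be split into parts of 2, so part or all of the excess may come from the shared controls. The shared count was 781 without Tet1KO A and 939 without DKO A. Of the 1412 genes, 68 were also called between N1300T and DKO.

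N1300T against DKO compares the mutant genotype with the Tet2 knockout genotype. Peg13, an imprinted non-coding RNA inside Trappc9, was higher in N1300T by 4.50 ± 0.38 (adjusted p 1.17e-06), at 1.53 ± 0.224 beside 0.0673 ± 0.0316 CPM. Also higher were Rbm12b1, an RNA-binding protein gene (2.05 ± 0.18), Trpm1, a cation channel (1.66 ± 0.22), and Hal, histidine ammonia-lyase (1.08 ± 0.17). Nlrp4a (1.06 ± 0.16), Tekt1 (1.12 ± 0.19), Vwf (1.10 ± 0.24) and Blnk (1.09 ± 0.22) were the other largest positive differences. Beside Tet1KO, however, Rbm12b1, Trpm1, Hal and Nlrp4a were low in DKO rather than raised in N1300T. For Tekt1 and Blnk too, every DKO library lay below every Tet1KO library, and N1300T overlapped Tet1KO. In CPM per library, Rbm12b1 ran from 2.97 to 4.12 in Tet1KO and from 2.31 to 3.44 in N1300T. Trpm1 ran from 18.5 to 29.6 and from 8.76 to 20.8. Peg13 was higher in N1300T than in Tet1KO as well, by 1.11. The larger part of its 4.50 came from a low level in DKO (0.0344 to 0.0973 CPM beside 0.407 to 0.902 in Tet1KO). Fkbp6 fell from 1.36 ± 0.135 to 0.0822 ± 0.0965 CPM, Slc15a2, a peptide transporter, by 2.67 (SE 0.22), Sh3bgrl by 2.66 (SE 0.27), Ushbp1 by 1.89 (SE 0.15) and Odf2l by 1.66 (SE 0.32). Nefm, a neurofilament gene, was also lower (-1.61 ± 0.42). Its N1300T libraries (0.188 to 1.32 CPM) overlapped those of Tet1KO (0.479 to 1.31 CPM), with DKO above both. Interferon-related genes moved both ways, with Gbp2 lower (-1.49 ± 0.20) and Oas1a higher (1.11 ± 0.21). Gbp2 ran from 0.570 to 0.620 CPM in the Tet1KO libraries, near its 0.590 to 1.08 CPM in N1300T.

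This comparison called 597 genes, 273 higher and 324 lower in N1300T (edgeR, adjusted p under 0.05), of which 18 were over 2-fold higher and 67 over 2-fold lower. Against Tet1KO, 196 of the 597 were called only in DKO, 143 only in N1300T and 183 in neither. Scaling by library size alone moved the share of higher calls from 45.7% to 29.1%. The count was 126, 381 and 107 without DKO A, B and C, 347 and 387 without N1300T 49 A and B, and 372 and 1053 without N1300T 81 B and C. DESeq2 called 1073 genes, N1300T 49 alone 366 and N1300T 81 alone 379, and 129 genes were called with both in the same direction.

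Imprinted genes were lower in N1300T than in DKO, with 10 lower and 2 higher of 40 (13 and 3 adjusted over the list alone, adjusted p 0.000337), among them Plagl1 (-1.35 ± 0.09), Zdbf2 (-1.15 ± 0.06), Igf2 (-0.94 ± 0.16) and Peg10 (-0.97 ± 0.14), with H13 higher (0.86 ± 0.06). With an estimated correlation the adjusted p was 0.335, and the other 8 lists named here also lost their call (adjusted p 0.185 to 0.728), while the Y-linked list kept it (adjusted p 0.00721). Trophoblast genes had 4 lower of 18 (6 adjusted over the list alone, adjusted p 0.000337), the keratins Krt8 (-0.53 ± 0.08) and Krt18 (-0.70 ± 0.10) among them, and 2 of 14 off chromosomes 6, 8 and 11. For p53 targets 6 of 29 were lower (15 lower and 2 higher adjusted over the list alone, adjusted p 0.000337), with Pmaip1 (-0.37 ± 0.06) and Mdm2 (-0.39 ± 0.10). The p53 count was 1, 2 and 1 without DKO A, B and C, 2, 2 and 10 without N1300T 49 A, B and C, and 3, 2 and 12 without N1300T 81 A, B and C. Cholesterol synthesis had 4 higher of 24 (9 higher and 1 lower adjusted over the list alone, adjusted p 0.000219), with Fdps (0.34 ± 0.08) and Insig1 (0.34 ± 0.08), and 2, 1 and 2 without N1300T 49 A, B and C and 2 without N1300T 81 A or B. Without DKO A, B or C edgeR called 0 cholesterol genes, with 9, 9 and 12 at an unadjusted p under 0.05. Naive pluripotency genes had 2 higher of 22 (2 adjusted over the list alone, adjusted p 0.00613), Prdm14 (0.33 ± 0.08) and Nr0b1 (0.27 ± 0.06). That count was 1 without DKO B, N1300T 49 A or B, or N1300T 81 A or B, and 0 by edgeR without DKO A or C (5 members at an unadjusted p under 0.05 in each). Without N1300T 49 C, 1 naive gene was also called lower. Wnt targets (1 lower of 19, 2 lower and 1 higher adjusted over the list alone, adjusted p 0.0140) included Wnt8a (-1.32 ± 0.26), and ERK pathway genes (1 lower of 20, 2 adjusted over the list alone, adjusted p 0.0163) included Phlda1 (-0.51 ± 0.14). Wnt calls were 2 lower without N1300T 49 C, 2 lower and 1 higher without Tet1KO B or C, 4 lower and 1 higher without N1300T 81 C and 0 by edgeR without DKO C (5 unadjusted). ERK calls were 5 without N1300T 81 C and 0 by edgeR without Tet1KO A, the 3 DKO libraries, N1300T 49 A or B, or N1300T 81 A or B (3, 4, 2, 3, 3, 3, 3 and 3 unadjusted). Glycolysis and hypoxia (adjusted p 0.000378, median 0.22) and Hox genes (adjusted p 0.0444, median -0.29) were called as sets with 0 members called by edgeR, 12 and 2 members at an unadjusted p under 0.05, 1 and 0 by DESeq2 and 0 and 1 by limma-voom. Without N1300T 81 C, 10 glycolysis genes were called higher, and 2 without N1300T 49 C or Tet1KO C and 1 without Tet1KO B. For Hox genes there were 2 lower without N1300T 81 C and 1 lower without N1300T 49 C. Several genes named here differed through DKO. In CPM per library, N1300T overlapped Tet1KO for Krt8, Krt18, Pmaip1 and Wnt8a, with DKO above both. It also overlapped Tet1KO for H13, Fdps, Insig1 and Prdm14, with DKO below both. N1300T lay below both other groups for Plagl1, Zdbf2, Igf2 and Peg10 and above both for Nr0b1, and overlapped both for Phlda1.

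A count of genes apart in both N1300T preparations from both other groups asks which changes both preparations share. It cannot tell the mutation from shared descent, which the labels do not give. The rule took 39 genes, 12 higher and 27 lower, beside 5 and 7 genes for the other 2 ways of pairing the 4 groups. Among the lower genes were the Y-linked Eif2s3y (-7.64 against Tet1KO and -6.88 against DKO) and Zfp263, with few counts in N1300T. Lower in both preparations were Hydin, a gene of motile cilia (1.603 ± 0.152 and 1.45 ± 0.226 CPM against 11.5 ± 0.571 in Tet1KO and 4.196 ± 0.463 in DKO), Slc15a2 (0.527 and 0.6500 against 4.55 and 3.700 CPM), Sh3bgrl, As3mt, Maoa, a monoamine oxidase, Msantd4 and Ushbp1. Higher in both were Gnat1, a transducin subunit (5.22 ± 0.2702 and 5.57 ± 0.721 CPM against 2.22 ± 0.2995 and 3.22 ± 0.316), Tgm3, Foxd3, Itpka, Gpc3 and Zfp428. Of the 40 imprinted genes tested, 4 were among the 39: Zdbf2 (chromosome 1, 63200358 to 63314576) stood at 102 ± 7.59 and 104 ± 6.77 CPM against 201 ± 12.6 in Tet1KO and 229.8 ± 8.99 in DKO, Plagl1 (chromosome 10, 13090832 to 13131694) at 53.1 and 57.4 against 107 and 140.3 CPM, Peg10 (chromosome 6, 4747306 to 4760517) at 65.1 and 63.8 against 143 and 126 CPM, and Peg13 (chromosome 15, 72805602 to 72810324), the 1 of the 4 that was higher, at 1.598 and 1.46 against 0.705 and 0.0673 CPM. The count was 16 and 13 without DKO A and C, 17 and 23 without N1300T 49 A and B, 18 without N1300T 81 A and 76 with DESeq2. By the same rule 872 genes were apart in Tet1KO from the other 3 groups (485 without Tet1KO A), 69 in DKO, 12 in N1300T 49 and 24 in N1300T 81.

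**Figure D4:**
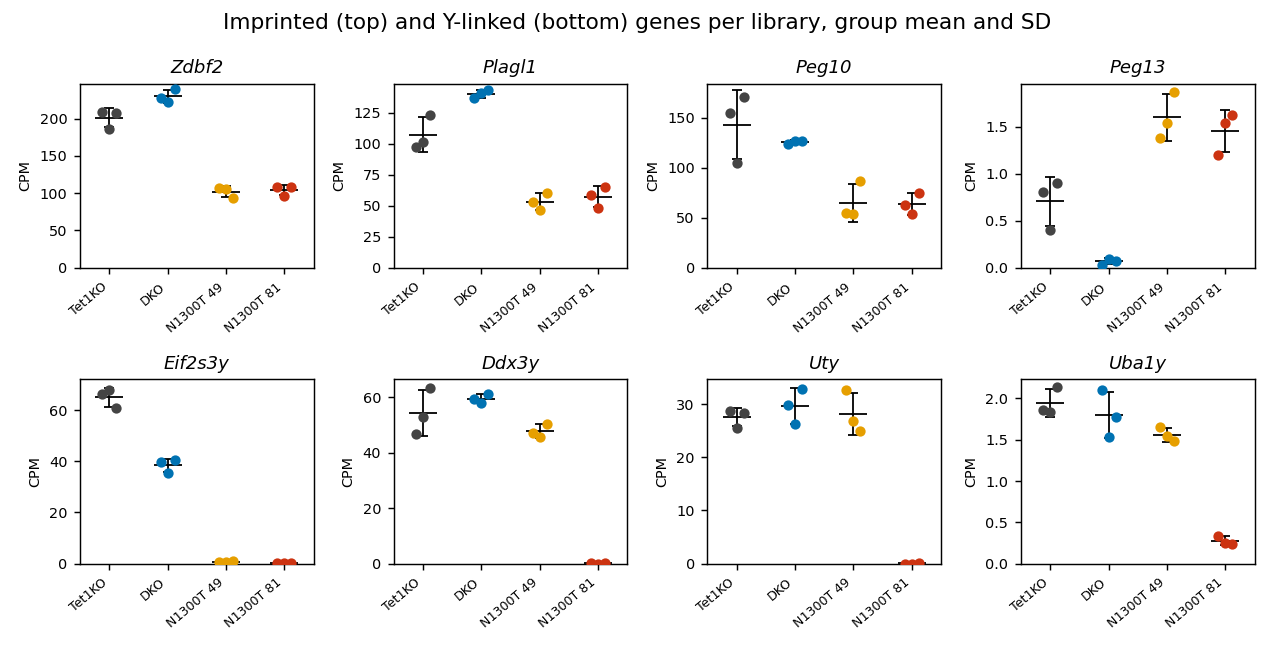
Expression in CPM (vertical axes, linear) of 4 imprinted genes (top) and 4 Y-linked genes (bottom) in each library (points), with group mean and SD (bars). Zdbf2, Plagl1 and Peg10 are lower and Peg13 higher in both N1300T groups than in Tet1KO and DKO, and Ddx3y and Uty are near 0 only in N1300T 81.

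N1300T 49 against N1300T 81 measures how far 2 preparations of 1 genotype differ. Ddx3y and Uty, both Y-linked, differed most of the named genes. Ddx3y, an RNA helicase gene (chromosome Y, 1260715 to 1286628), stood at 47.8 ± 2.42 CPM in 49 and 0.0571 ± 0.0677 CPM in 81, and Uty, a histone demethylase paralog (chromosome Y, 1085187 to 1245773), at 28.1 ± 3.96 and 0.04396 ± 0.0761 CPM. Eif2s3y, a translation initiation factor gene (chromosome Y, 1010562 to 1049134), was at 0.7304 ± 0.175 CPM in 49 and 0.1497 ± 0.0704 CPM in 81, beside 65.00 ± 3.64 CPM in Tet1KO and 38.5 ± 2.58 CPM in DKO. Fmr1nb, on the X chromosome, fell from 33.3 ± 3.43 CPM in 49 to 0.567 ± 0.366 CPM in 81, and Sohlh2 was also higher in 49 (1.54 ± 0.31), while Arhgap30 was lower in 49 (2.63 ± 0.773 against 21.2 ± 2.07 CPM), as were Dnah12 (-1.57 ± 0.18), Hsf2bp (-1.04 ± 0.09) and the imprinted genes H19 (-1.03 ± 0.12) and Zrsr1 (-0.94 ± 0.08). The imprinted gene Grb10 was higher in 49 (0.96 ± 0.12). edgeR called 58 genes, 31 higher and 27 lower in 49, and DESeq2 called 108. Of the lists, the Y-linked one was called with 4 of 4 members (4 adjusted over the list alone, adjusted p 8.33e-22, and 0.00107 with an estimated correlation). Neuroectoderm (1 higher of 15, 2 adjusted over the list alone) was also called with adjusted p 0.00113, as were p53 targets and glycolysis and hypoxia, each with 0 members by edgeR, DESeq2 and limma-voom and with 5 and 4 members at an unadjusted p under 0.05 (2 and 0 adjusted over the list alone). With an estimated correlation adjusted p of these 3 lists was 0.943.

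Because all 4 Y-linked genes tested fell to 0.274 CPM or less in N1300T 81, their mean change over both N1300T preparations is not a level that either held, and it is given here per preparation. Against Tet1KO, Ddx3y changed by -0.19 in 49 (adjusted p 0.305) and -9.91 in 81 (adjusted p 7.87e-15), Uty by 0.03 in 49 (adjusted p 0.908) and -9.32 in 81 (adjusted p 1.06e-12), and Eif2s3y by -6.51 and -8.76. The 81 counts are so few (8 for Ddx3y, 6 for Uty) that these fitted values depend on the prior count. The list was called lower in N1300T with 4 of 4 members against Tet1KO (4 adjusted over the list alone, adjusted p 2.94e-08) and 4 of 4 against DKO (4 adjusted over the list alone, adjusted p 1.05e-12). In DKO, Eif2s3y also fell against Tet1KO, by 0.75 (SE 0.09, adjusted p 2.83e-05).

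Medians of the tested genes per chromosome showed where the Tet1KO libraries differed from the rest. Relative to the mean of the 12 libraries, the 724 genes of chromosome 6 had medians of 0.18, 0.07 and 0.07 in Tet1KO A, B and C, and the other 9 libraries lay between -0.04 and -0.02. Chromosome 8 (824 genes) had 0.13, 0.06 and 0.05 in the same libraries, and chromosome 11 (1327 genes) had -0.12, -0.03 and -0.05. Against Tet1KO, the N1300T medians were -0.14, -0.11 and 0.10 for chromosomes 6, 8 and 11, and those of DKO were -0.16, -0.10 and 0.07. Between N1300T and DKO they were 0.01, -0.01 and 0.01. No p-value was attached to these medians.

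**Figure D5:**
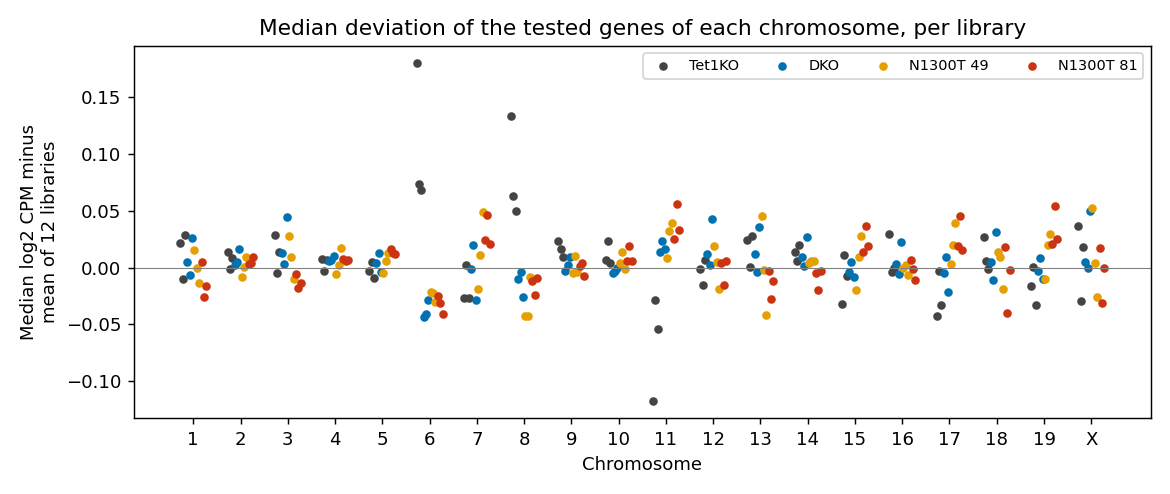
Median log2 CPM of the tested genes of each chromosome (horizontal axis) minus the mean of the 12 libraries (vertical axis, log2), 1 point per library coloured by group. The 3 Tet1KO libraries lie above the others on chromosomes 6 and 8 and below them on chromosome 11, furthest in Tet1KO A.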

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

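The tests of the chromosomes, of Tet1KO A, of the number of Tet1KO sets, of equal Y-linked shares in N1300T 49, of overlap with the imprinted list and with all lists, of neighbouring genes with none left out and of parental clones were chosen only after the results they measure, or closely related ones, had been seen. The bounds for the other tests were set beforehand.

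The effect of the N1300T genotype against Tet1KO differed between the 2 preparations for the named genes below, by the edgeR test of 49 against 81. The difference in log2 fold change, 49 minus 81, was 9.73 for Ddx3y, 9.36 for Uty and 2.25 for Eif2s3y among Y-linked genes. It was 1.35 for Gata4, an endoderm factor (2.09 in 49 and 0.75 in 81), 0.81 for Gap43 (-0.46 and -1.26) and 0.48 for Tex19.1 (0.85 and 0.37). Maoa differed by 0.83 (-0.90 and -1.73) and Ushbp1 by -1.14 (-1.91 and -0.77). Each library was left out in turn, and no outlier statistic was computed within groups of 3.

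Tet1KO stood apart from all 3 other groups at 872 genes. Of these, 26.1% lay on chromosomes 6, 8 and 11, while 82.05% of the tested genes lay elsewhere or had no chromosome assigned. On chromosomes 6 and 8 most were higher in Tet1KO (53 of 62 and 63 of 81), while on 11 most were lower (66 of 85). Extra copies of chromosomes 6 and 8 in part of the Tet1KO cells may contribute. The bounds of this test, over 50% for a cause of the whole pattern and under 25% against it, leave it open. Of the 872 genes, 644 lay on other chromosomes or had none assigned. Tet1KO A alone is argued against, since 485 genes were apart without it, 473 of them among the 872 and in the same direction, beside 51 for DKO in the same fit, and so is depth, since thinning to the lowest total gave 88.2% of the count (769 genes, 727 of them among the 872). An effect of altered Tet2 shared by DKO and N1300T cannot be told apart from a property of the Tet1KO cells, because there is 1 set of Tet1KO libraries.

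Y-linked transcripts fell in different ways in the 2 N1300T preparations. In N1300T 49, Eif2s3y kept 1.12% of its Tet1KO level and Uty 102%, so the largest share was 90.9 times the smallest, which argues against loss of the whole Y chromosome in part of the cells. In N1300T 81, Ddx3y, Uty and Eif2s3y kept 0.105% to 0.230%, but Uba1y, at 1.95 CPM in Tet1KO, kept 14.1%, between the bounds of under 5% and over 20% set for loss of the whole Y chromosome, so that stays open, as reads from its X-linked paralog may add to a count this low. The levels that differed between 49 and 81 do not follow the genotype label, which both share. Eif2s3y was low in both and among the genes apart, but shared descent cannot be told apart from the genotype there.

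Zdbf2, Plagl1 and Peg10 were lower and Peg13 higher in both N1300T preparations than in both other groups. An overlap of 4 of 40 imprinted genes with the 39 genes apart, where 0.0974 are expected, has a two-sided Fisher exact p of 2.58e-06, which carries no weight by itself, since the overlap had been seen when this list was taken. With all 31 lists tested in the same way, its adjusted p was 7.99e-05 and the next lowest 0.1505 (Y-linked), which argues against chance overlap, although genes were treated as independent. Yet of the 58 genes called between 49 and 81, which share a genotype label, imprinted genes gave 1 higher and 3 lower of 40. Imprinted genes thus also differed between preparations of 1 label, and the overlap does not by itself point to the genotype. The 31 neighbours of the 3 lower genes within 1 Mb had a median of -0.16 against Tet1KO (5 called lower, lowest -1.99), but genes apart and imprinted genes had been left out of them, so this excludes nothing. With every other tested gene kept, the median was -0.11 over 13 genes around Zdbf2 (median absolute deviation 0.16, 2 called lower) and -0.14 over 12 around Plagl1 (0.34, 3 called lower), beside -0.96 for each of the 2 genes. This argues against loss of 1 copy of the whole of these 2 windows in all cells. Loss in part of the cells would shift the neighbours less and was not tested. Around Peg10 (-1.16) the median was -0.33 over 10 genes (0.54, 2 called lower), between the bounds of -0.5 and -0.25, so loss there stays open. The 2 called lower were Pon3 (-1.99) and Sgce (-1.15), a member of the imprinted list that was also lower against DKO (-0.95). Losses shorter than a window were not tested, and 1700039I01Rik, inside Zdbf2 and looked up after its value was seen, was itself among the 39 (-0.95). Altered imprinting through altered Tet2 may be considered as a hypothesis, but 0 labels give a parental clone, so descent of both preparations from 1 cell with these levels cannot be told apart from it.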

How the results depend on the processing

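The fits with halved counts, without chromosomes 6, 8 and 11, and without Tet1KO A together with those chromosomes were chosen after seeing the data, and the other alternatives beforehand. At the smallest fold simulated the test recovered 28% of changed genes in DKO against Tet1KO, where halved counts called 2427 genes. The cause was not tested for any change below unless the setting itself removes genes or libraries.

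N1300T against Tet1KO called 2520 genes, 234 against a fold of 1.5 and 1032 without Tet1KO A and chromosomes 6, 8 and 11. Leaving out each library gave 1388 to 2575 (lowest without Tet1KO A), and all other settings gave 1739 (N1300T 49 alone) to 3323. DKO against Tet1KO called 2399, 238 against a fold of 1.5, 1041 without Tet1KO A and the 3 chromosomes, and 1386 to 2575 without single libraries (1386 without Tet1KO A, 1420 and 1402 without DKO A and C). N1300T against DKO called 597, 1073 with DESeq2, 1481 without the low-count filter, 32 against a fold of 1.5, 380 without Tet1KO A and the 3 chromosomes, 366 with N1300T 49 alone and 379 with N1300T 81 alone. Single libraries left out gave 107 to 1053 (lowest without DKO C, highest without N1300T 81 C). Between 49 and 81 there were 58 calls, 108 with DESeq2, 244 without the filter, 10 against a fold of 1.5, 38 without the 3 chromosomes and 38 without Tet1KO A as well, and 39 to 80 without single libraries. Genes apart in both N1300T preparations numbered 39, 76 with DESeq2, 111 without the filter, 8 against a fold of 1.5, and 13 to 49 without single libraries (lowest without DKO C). The overlap of 1412 was 598 without Tet1KO A and the 3 chromosomes and 781 to 1486 without single libraries (lowest without Tet1KO A). DESeq2 called again 2465, 2337 and 571 of the genes called in the first 3 comparisons.

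The replicate letters did not pair the libraries by rule: 7 of 18 same-letter pairs correlated above 0.1. All 7 were among Tet1KO, 49 and 81 (9 pairs, 0.07 to 0.31), all 3 of Tet1KO with 81 included, and pairs with DKO lay between -0.04 and 0.04, although 10 of 12 libraries correlated best with their own letter, a hint from the data. With the letter as a block the counts were 3323, 3281, 1497 (N1300T against DKO), 105 (49 against 81) and 117 (genes apart), and 2 Hox genes were lower in N1300T than in DKO. Against Tet1KO the block gave 2496 calls for 49 alone and 2770 for 81 alone, beside 1739 and 1951 without it. List counts that moved by at least 3 genes and over 1.5 times in a direction were these. N1300T against DKO had 10 glycolysis genes higher, 14 p53 targets and 5 primitive endoderm genes lower, 1 neuroectoderm gene higher and 4 lower, 1 and 3 for mesendoderm and 3 and 5 for interferon. N1300T against Tet1KO had 4 higher and 6 lower for ERK, 2 and 6 for glycolysis and 2 and 8 for DNA methylation. DKO against Tet1KO had 7 and 4 for ERK, 6 and 3 for neuroectoderm, 10 and 7 for imprinted genes, 1 and 5 for recombination and 2 and 5 for G2 and mitosis.

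Lists called in the 4 comparisons numbered 10, 15, 10 and 4. With an estimated correlation they were 1, 0, 1 and 1, and with fry 18, 17, 7 and 1. Of the 39 calls the replicate block lost 1, and it gained 2, while fry lost 9 and gained 13. Those lost by fry, with its adjusted p, were glycolysis in DKO against Tet1KO (0.408), p53 targets (0.0654), Hox (0.0816), ERK (0.178), Wnt (0.0963) and glycolysis (0.394) in N1300T against DKO, and neuroectoderm (0.708), p53 targets (0.708) and glycolysis (0.833) in 49 against 81. Of the 20 calls of N1300T against Tet1KO or DKO, 49 alone lost 4, mesendoderm and Wnt against Tet1KO (both 0.0626) and ERK and glycolysis against DKO (both 0.09601). N1300T 81 alone gained 2 and lost 3, LIF and STAT3 targets against Tet1KO (0.0658) and Hox (0.126) and Wnt (0.125) against DKO. The first principal component held 36.1%, 28.2% over all genes and 44.99% after a variance stabilising transformation. Of 279 called results for named genes, DESeq2 kept 276, and between 236 and 275 stayed called when any 1 library was left out, with no reversal. Only uncalled results reversed. Without single libraries, log2 values ran from -0.0159 (without Tet1KO B) to 0.179 for Tet1 in N1300T against Tet1KO and from -0.113 to 0.0228 (without DKO A, and 0.00772 without 49 A) for Tet3 in N1300T against DKO. In 49 against 81 they ran from -0.124 to 0.0218 (without 81 B) for Tdg, from -0.0279 (without 81 B) to 0.136 for Tet1 and from -0.127 to 0.00513 (without 81 A) for Tet2. For Tet3 they ran from -0.0657 (without 81 B) to 0.144, with -0.00856 and -0.0600 without 49 B and C. List directions reversed with adjusted p of 0.568, 0.418 and 0.946 for neuroectoderm, glycolysis and protocadherins (N1300T 81 alone against Tet1KO) and 0.876 for Polycomb (fry, DKO). Against DKO these were 0.966, 0.491 and 0.966 for the two-cell-like, neuroectoderm and integrated stress response lists (49 alone) and 0.990 (block) and 0.703 (81 alone) for LIF and STAT3 targets.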

Other observations

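The list counts without single libraries were chosen after the result was seen, and the splits of the libraries were planned.

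Other lists showed single genes moving in N1300T against Tet1KO without a call of the list. Germline genes under promoter methylation had 10 higher and 6 lower of 34 (10 and 7 adjusted over the list alone, adjusted p 0.307), with Meioc (0.96 ± 0.09) and Tex19.1 (0.61 ± 0.06) up and Syce1, of the synaptonemal complex, down (-1.31 ± 0.17), and 10 and 3 without Tet1KO A. Imprinted genes had 10 lower and 4 higher of 40 (12 and 6 adjusted over the list alone, adjusted p 0.0632), with the growth factor Igf2 (-1.96 ± 0.16) and Phlda2 (-0.98 ± 0.09) down and Meg3 up (0.54 ± 0.08). In DKO against Tet1KO the imprinted list had 6 higher and 7 lower (10 and 8 adjusted over the list alone, adjusted p 0.545), with a median of 0.05 and a mean of -0.05. Primitive endoderm had 6 higher and 2 lower of 22 (6 and 2 adjusted over the list alone, adjusted p 0.0599), with Gata4 (1.42 ± 0.18) and Amn (1.34 ± 0.23), and 2 higher with 1 and 2 lower without Tet1KO A and C. DNA methylation machinery had 5 lower of 18 (7 lower and 1 higher adjusted over the list alone, adjusted p 0.0940), with Uhrf1 (-0.23 ± 0.05), 3 lower without Tet1KO A, B or C, and 1 higher as well without Tet1KO C, DKO C, 49 A or 81 A. Homologous recombination and Fanconi repair had 3 higher and 6 lower of 34 (3 and 7 adjusted over the list alone, adjusted p 0.190), with Fancm up (0.58 ± 0.06) and Rad50 down (-0.76 ± 0.09), and 2 and 2 without Tet1KO A. Polycomb genes had 3 higher and 3 lower of 23 (3 and 3 adjusted over the list alone, adjusted p 0.870), with Phf19 up (1.01 ± 0.14) and Ezh2, the H3K27 methyltransferase, down (-0.35 ± 0.05), 1 and 3 without Tet1KO A, and 2 and 1 of 13 off chromosomes 6, 8 and 11.

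Smaller counts in the same comparison were 3 higher of 22 for naive pluripotency (3 higher and 2 lower adjusted over the list alone), including Nr0b1 (0.24 ± 0.06), with 5 called without Tet1KO B and 0 by edgeR without Tet1KO A (4 unadjusted), and 3 higher and 4 lower of 18 for trophoblast (3 and 5). Naive calls were 3 higher and 1 lower without Tet1KO C or 81 B, 2 and 1 without 81 A and 2 and 2 without 49 B. Neuroectoderm had 3 and 2 of 15 (3 and 2), with Crabp2 up (1.73 ± 0.13), 5 and 1 without Tet1KO C and 3 and 4 without N1300T 81 C. Fibroblast markers had 4 and 1 of 18 (6 and 2, with 3 and 2 called without Tet1KO B and 6 and 2 without N1300T 81 C), with Fbln2 up (0.96 ± 0.12) to 11.4 ± 1.295 CPM. Blood specification had 3 and 1 of 17 (3 and 1), with Cebpa up (1.28 ± 0.20), and interferon response 2 and 2 of 32 (1 and 2). Interferon calls were 4 and 2 without 49 C or 81 C, 2 and 1 without Tet1KO B, and 1 and 2 without each of the other 9 libraries. Clustered protocadherins had 3 and 1 of 23 (3 and 1), with Pcdhga12 up (1.29 ± 0.19). Their lower member lost its call without Tet1KO A or C, any 1 DKO library, 49 A or B, or 81 B, and 2 were lower without 81 C. Heat shock had 3 and 3 of 14 (3 and 5), with Hsph1 up (0.45 ± 0.06), and 1 and 1 without Tet1KO A or C. ERK pathway genes had 4 lower of 20 (4 higher and 6 lower adjusted over the list alone, median 0.04, mean -0.04), with Spry4 (-0.64 ± 0.11) and Dusp6 (-0.54 ± 0.11), feedback inhibitors of the pathway. ERK calls were 3 higher and 5 lower with DESeq2 and 3 and 3 without 81 B. They were 1 and 3 without Tet1KO A or 49 B, 1 and 4 without Tet1KO B, 2 and 3 without Tet1KO C, 2 and 4 without 49 A and 6 lower without 49 C or 81 C. TET enzymes and base excision repair had 3 lower of 24 (3 lower, 1 without Tet1KO A, and 1 of 17 off chromosomes 6, 8 and 11). Glycolysis and hypoxia had 2 lower of 30 (1 lower), with 6 lower without Tet1KO C, 7 lower without N1300T 81 B, 2 higher without Tet1KO B, 2 higher and 2 lower without N1300T 81 C and 0 by edgeR without Tet1KO A (4 unadjusted). The two-cell-like state had 1 lower of 6 (1 lower), and 0 by edgeR without Tet1KO A or C (1 unadjusted in each), and the Rhox cluster 1 lower of 3 (1 lower). G2 and mitosis had 1 lower of 34, Kif23 (-0.21 ± 0.06), and none adjusted over the list alone. Without Tet1KO C it had 4 lower and 1 higher, without 81 A 2 lower, without Tet1KO B, 49 B, 49 C or 81 C 1 lower and 1 higher, and without Tet1KO A 0 by edgeR (2 unadjusted). Mitochondrially encoded genes had 0 called of 13 by edgeR, DESeq2 and limma-voom, with 1 at an unadjusted p under 0.05, and 5 lower without N1300T 49 A and 1 lower without N1300T 81 A. Adjusted p of the set test for the lists in this paragraph lay between 0.0632 and 0.870. Median and test differed in sign from the mean for protocadherins (median 0.103, mean -0.000783).

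Other splits of the same libraries were run for each count. For N1300T against Tet1KO, a fit of the 9 libraries in 2 groups called 1911 genes, the most of all 84 splits (1 of 84), with 52 in the highest other, so an arbitrary grouping of libraries is argued against at this number of splits. For N1300T against DKO the fit called 440, and 2 of 84 splits gave as many, the other being 845 genes when N1300T 49 B, 81 A and 81 B were set against the remaining 6. For DKO against Tet1KO (2893, highest other 0 with edgeR) the real split was 1 of 10 and for 49 against 81 (39, highest other 208) it was 1 of 2 splits of 10 as large, and 10 splits are too few for a share under 0.05. The split with 208 genes set 49 A, 49 C and 81 C against 49 B, 81 A and 81 B, which points to a structure of the samples that crosses both preparations. Among 100 splits into 4 groups, the real one alone reached 39 genes apart (1 of 100, highest other 1) and 1412 shared genes (1 of 100, highest other 81). Splits of single libraries mix preparations within a group, which adds spread and leaves few calls. These shares therefore show that libraries of 1 preparation resemble each other, and do not test the genotype label. The other 2 ways of pairing whole preparations gave 5 and 7 genes apart.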
